A study of Mus musculus with 202 samples.

How the data were processed

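Single cells of a mouse pancreatic ductal adenocarcinoma line were cultured, trypsinised, stained for E-cadherin and sorted by flow cytometry into a positive and a negative fraction, per the labels' protocols. Cells were captured on a Fluidigm C1, a microfluidic device that isolates single cells in chambers, and their RNA was amplified with SMARTer chemistry and made into Nextera XT libraries. This chemistry carries no molecular identifiers and does not mark strand, so genes that overlap on opposite strands cannot be told apart. The submitters' processing notes name FastQC 0.11.5, kallisto without a version, and build mm10. The transcript index, the summing of transcripts to genes and any filter on cells are not given in the sources used here.

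The authors deposited 1 table of 28987 genes with log2 values for 202 libraries. Back-transformed as 2 to the power of the value minus 1, each library summed to between 933711 and 987134, so the values were read as log2(TPM + 1). The authors' own mean of log2 values per group matched the mean of the cells. Columns of the deposited table that treat cells as replicates (fold changes and p-values) were not used here. The table gives no symbol for 795 genes, and 92 symbols stand on several rows, where the row with the highest mean was taken. Of the gene identifiers, 27458 matched GENCODE M21, which is on the same build (GRCm38, mm10) and gave the coordinates. List members without a matching symbol were looked up by identifier.

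TPM keeps no read depth, so no counting error per level can be given. An exact 0 means only that a gene is listed at 0. Because TPM is relative within a cell, a large shift in a few abundant genes moves all others. Mitochondrial genes took up to 66.4% of TPM in a cell, and mt-Atp8 up to 57.6%.

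Groups were taken from the sample labels. The library names carry 1 of 3 suffixes, which were treated as 3 library sets; what the suffix stands for is not stated. Set sizes were 28, 39 and 37 Ecad+ and 33, 32 and 33 Ecad- libraries. Pairs of libraries with a Pearson correlation over 0.97 across all genes were treated as 1 cell with 2 libraries. There were 5 such pairs, 4 Ecad+ and 1 Ecad-, each across library sets. Their TPM values were averaged for pooled values, while each library stayed in its own set for within-set values, so the sets share 5 cells. Pairs were not tested against sampling noise, which needs counts. Library names also carry a number, which is lower in all Ecad+ than in all Ecad- libraries, so no number occurs in both groups. An effect tied to this number, whose meaning is not stated, cannot be told apart from the sorted group. Libraries with the same number in different sets were otherwise no closer than others, with a median correlation of 0.80 against 0.81.

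The group level was the arithmetic mean of TPM over cells, and the ratio was log2 of the Ecad- level plus 1 over the Ecad+ level plus 1. Such a ratio understates the change of low genes. Each group is 1 sample, so no test was made. Shares of cells have exact Clopper-Pearson 95% intervals, which treat cells as independent and cover counting error only. Gene lists were fixed before the data were examined. They cover epithelial, mesenchymal, class I antigen presentation, integrated stress response, unfolded protein response, G1/S, G2/M, cell cycle inhibitor, interferon, TGF-beta, hypoxia and glycolysis, cholesterol, immediate early, heat shock, NF-kB, checkpoint, MAPK, ductal, autophagy, oxidative stress, mitochondrial and ribosomal genes. They also cover markers of immune, fibroblast, endothelial, hepatocyte, and acinar and endocrine cells. Some lists are close to what the study's title names. Members needed a mean of at least 5 TPM over all cells and a value above 0 in at least 10% of cells. The list median was placed as a percentile among 10000 random lists of the same size, matched on mean level in 20 bins, as a description of these cells.

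Genes named in the text follow a rule fixed beforehand. It takes 12 genes whatever their values and up to 4 members of each list with the largest absolute ratio. It also takes the 10 higher and 10 lower genes with the largest minimum ratio over the 3 sets, among genes with a mean of at least 20 TPM, above 0 in at least 25% of cells and of 1 sign in all sets. In that ranking 11 gene models without a proper symbol were passed over. Sqstm1, Pdia3, Atp6v1d, Atp6v0b, Flcn and Rragc were named after their values were seen.

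Alternatives were a 10% trimmed mean, means of log values, centring on the all-gene median, rescaling each cell without mitochondrial and ribosomal protein genes, pseudocounts of 0.1 and 10, list floors of 0 and 50 TPM, cell filters, each library set left out, and sets weighted equally. The trimmed mean left out 10% of a group's cells in total, 5% at each end. Added after seeing the data were all 202 libraries counted separately, the 10% of cells with the fewest genes left out, cells with a mitochondrial share of TPM under 1% left out (40 Ecad- and 1 Ecad+, not for mitochondrial genes), and rescaling without mt-Atp8. No doublet caller was run, and the 5% of cells with the most genes were left out as an alternative.

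The steps were tested on simulated data made by splitting the 100 Ecad+ cells at random and multiplying 200 genes by known factors in one part. Median ratios were 0.92 for 50 genes raised 2-fold, 1.90 for 4-fold, -1.10 for 0.5-fold and -1.96 for 0.25-fold. All 3 simulated sets gave the right sign for 98% to 100% of these genes. Of 100 unchanged lists, 3 fell outside the central 95% of random lists. Among 6635 unchanged genes, 22.2% had 1 sign in all 3 sets. Both parts were Ecad+ cells, so the simulation lacked the group differences in genes above 0 and in mitochondrial share described below. Lists of genes that vary together across cells were not simulated. These figures therefore describe the steps on similar cells, and not their error in the comparison of Ecad- with Ecad+ cells. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.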

Results

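The transcriptomes of single cells were measured in a mouse pancreatic ductal adenocarcinoma line of the KPC type, derived from a liver metastasis. Cultured cells were stained for E-cadherin, the epithelial adhesion protein encoded by Cdh1, and sorted into a positive and a negative fraction, here called Ecad+ and Ecad-. The comparison asks how the E-cadherin-negative cells differ, with endoplasmic reticulum stress and immune recognition named in the title of the study. The table holds 104 Ecad+ and 98 Ecad- libraries, each made from a single cell, in 3 library sets. The values of 5 pairs of libraries correlated at 0.984 to 0.994 over all genes, against 0.939 for the next closest pair. Each such pair was averaged and counted as 1 cell, which left 100 Ecad+ and 97 Ecad- cells. Whether a pair is 1 cell was not tested. Mitochondrial genes took 37.5% and 11.4% of TPM in the 2 libraries of the Ecad- pair. Shares in the 4 Ecad+ pairs were 34.7% and 30.7%, 19.3% and 27.3%, 22.5% and 39.9%, and 17.6% and 31.1%. This share can thus differ widely between libraries taken as 1 cell. No label names separate cultures or animals, so each group is 1 sample. The differences below have no replicate check, and no p-value is given. Levels are mean TPM (transcripts per 1000000) over cells, and ratios are log2 of Ecad- over Ecad+ with 1 TPM added to each mean.

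Ecad- cells had fewer genes above 0. The median was 8694 genes per cell in Ecad- cells (quartiles 8176 and 9336) and 10338 in Ecad+ cells (quartiles 10009.5 and 10895.8). The gap in medians was -1295, -2016.5 and -1625 genes in library sets 1, 2 and 3. With a threshold of 10 TPM it was -175.5 genes. Read depth per cell is unknown, since TPM does not keep it. Over the 7227 genes above the expression floor, the median log2 ratio was 0.31, and within sets it was 0.16, 0.44 and 0.26. This shift was -0.28 when means of log values were compared, and 0.0064 when mitochondrial and ribosomal protein genes were left out of each cell's total. Medians of gene lists are therefore given relative to the all-gene median. Ratios of single genes, and counts of genes higher or lower in each library set, are given as measured. Since the all-gene median was above 0 in each set, counts of genes higher in each set run high. For the 48 ribosomal protein genes, with a median of 0.13 relative to all genes, that count was 40. Mitochondrial genes took under 1% of TPM in 40 of 97 Ecad- cells and in 1 of 100 Ecad+ cells, here called low-share cells. Such a share can bear on RNA quality, so values without these cells, which leave 57 Ecad- and 99 Ecad+ cells, stand beside many of the gene groups. This filter was chosen after seeing the data, and the all-gene median was then 0.14. Low shares were uneven across sets, at 6 of 33, 12 of 32 and 22 of 33 Ecad- libraries in sets 1, 2 and 3. Differences between sets can therefore go with these cells.

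Cdh1, the gene of the sorted protein, was lower in Ecad- cells. Its mean was 37.9 TPM in Ecad+ and 16.1 TPM in Ecad- cells, a log2 ratio of -1.19. The ratio was -0.62, -1.05 and -1.96 in library sets 1 to 3. Cdh1 (ENSMUSG00000000303) lies on chromosome 8 at 106603351 to 106670246 in mm10. Its median was 35.1 TPM in Ecad+ cells (quartiles 22.8 and 48.0) and 11.5 TPM in Ecad- cells (quartiles 0.283 and 23.1). Cdh1 was above 0 in 100 of 100 Ecad+ cells (exact 95% interval 96.4% to 100%) and in 78 of 97 Ecad- cells, or 80.4% (71.1% to 87.8%). These intervals cover counting error only.

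Other epithelial genes were lower in Ecad- cells as well. Of 15 epithelial genes above the floor, 14 lay below the all-gene median and 11 were lower in each of the 3 library sets. The list median was -0.88 relative to all genes, at percentile 0 of 10000 random lists matched on level. Within sets it was -0.66, -0.95 and -1.36. Part of this difference went with the low-share cells: without them the list median was -0.54 at percentile 0.04, Krt19 stood at -0.99 and Cldn7 at -1.71. The list median within sets was then -0.71, -0.44 and -0.68. Cldn7, a tight junction claudin, went from 111 TPM in Ecad+ to 21.7 TPM in Ecad- cells, a log2 ratio of -2.31. The ductal keratins followed, with Krt7 at -2.00, Krt19 at -1.63 and Krt8 at -1.07. Krt19, on chromosome 11 at 100140810 to 100148665, had means of 899 and 290.0 TPM.

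Mesenchymal genes were not higher as a group. Just 7 of 35 list members were above the floor, and 6 of these lay below the all-gene median. The list median was -0.74 at percentile 0.59, with 0.09, -0.76 and -1.05 in the library sets, so set 1 differed in sign. The placing was not stable, as it was -0.41 at percentile 6.82 with means of log values, -0.29 without set 2, and -0.42 without low-share cells. Vim, which encodes the intermediate filament vimentin, was lower in Ecad- cells (454 and 265 TPM, log2 ratio -0.78). Fn1 stood at -0.78 and was higher in set 1 at 0.60. S100a4 stood at -0.58 and at 0.25 without set 3. Snai2, a transcriptional repressor of Cdh1, was the exception, with 3.51 TPM in Ecad+ and 22.4 TPM in Ecad- cells (log2 ratio 2.38, and 1.26, 1.77 and 3.38 within sets). Zeb1, another repressor of Cdh1, had a mean of 4.20 TPM in both groups, below the floor.

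Genes of the integrated stress response, the programme downstream of eIF2alpha phosphorylation and ATF4, were higher in Ecad- cells. Of 26 members above the floor, 23 lay above the all-gene median and 22 were higher in each library set, a count not centred. Their median was 0.99 at percentile 100, with 0.63, 0.86 and 1.61 within sets and 0.56 without set 3. Of the Ecad- cells, 40 of 97 were low-share cells. Without these the list median was 0.97 at percentile 100, with 0.84, 0.80 and 1.09 within sets. Single genes then stood lower, with Ddit3 at 3.07, Ppp1r15a at 1.79 and Atf4 at 1.16. Ddit3, which encodes the stress factor CHOP, had a mean of 31.1 TPM in Ecad+ and 562 TPM in Ecad- cells. Its log2 ratio was 4.13, and 2.98, 5.98 and 4.06 within sets. The median Ecad+ cell had 6.70 TPM of Ddit3 (quartiles 1.54 and 17.9) and the median Ecad- cell 264 TPM (quartiles 48.1 and 643). Ddit3 was above 0 in 85 of 100 Ecad+ cells (76.5% to 91.4%) and 87 of 97 Ecad- cells (81.9% to 94.9%), so the groups differed in level rather than in detection. Ppp1r15a, a phosphatase subunit acting on eIF2alpha, stood at 2.93. Trib3 stood at 2.61, Nupr1 at 2.60 and Atf4 at 2.22 (76.9 and 363 TPM). In mm10, Ddit3 lies on chromosome 10 at 127290774 to 127296288 and Atf4 on chromosome 15 at 80255184 to 80257541.

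**Figure D1:**
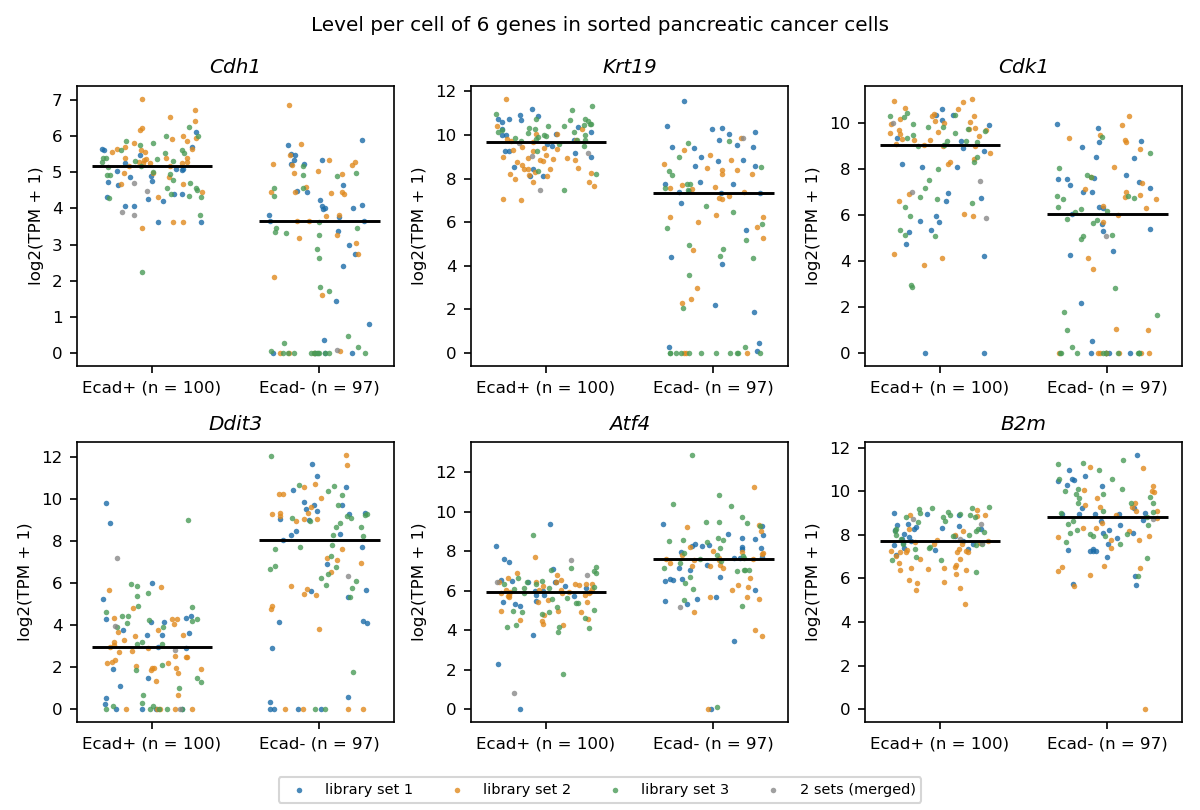
Level of 6 genes in each cell as log2(TPM + 1), for 100 Ecad+ and 97 Ecad- cells. Points are cells coloured by library set, grey points are cells merged from 2 libraries, and black lines are group medians. Ddit3 and Atf4 are higher in Ecad- cells, Cdh1, Krt19 and Cdk1 are lower, and cells of both groups overlap for each gene.

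Chaperones and other endoplasmic reticulum genes of the unfolded protein response differed less. The median of 35 members was 0.14 relative to all genes, at percentile 85.3, with 0.02, 0.16 and 0.23 within sets. Of these genes, 22 lay above the all-gene median and 13 below. Hspa5, which encodes the chaperone BiP, had means of 192 and 400 TPM (log2 ratio 1.05). Xbp1 stood at 0.72, with 0.02 in set 1. Crebrf stood at 3.14, Dnajb9 at 2.47, Txndc11 at 1.45 and Derl1 at 1.13. Without low-share cells Crebrf stood at 1.57, Dnajb9 at 1.46, Txndc11 at 0.78 and Derl1 at 0.65. The disulfide isomerase gene Pdia3 was lower, at -0.55. Xbp1 splicing was not analysed here.

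Autophagy and lysosome genes were higher in Ecad- cells by about as much as the stress response genes over all cells. Of 22 members, 20 lay above the all-gene median and 20 were higher in each library set, again not centred. As a group they had a median of 1.00 at percentile 100, with 0.69, 0.91 and 1.08 within sets. Without low-share cells it was 0.45 at percentile 100, below the 0.97 of the stress response list. Hexa then stood at 1.97 and Atp6v0d1 at 0.76. Over all cells, Hexa, a lysosomal hexosaminidase subunit, had 9.43 TPM in Ecad+ and 99.2 TPM in Ecad- cells (log2 ratio 3.26). Gla, another lysosomal hydrolase, stood at 2.39. Atp6v0d1 and Atp6v1h, subunits of the proton pump that acidifies lysosomes, stood at 2.36 and 2.24. Sqstm1, the autophagy receptor p62, stood at 2.14 with 212 and 941 TPM.

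Class I antigen presentation genes went both ways. The median of 11 members was -0.05 relative to all genes at percentile 40.6, with 6 members below and 5 above the all-gene median. With the trimmed mean the list median was 0.15 relative to all genes, and without low-share cells 0.12, so the list has no stable sign. B2m, the class I light chain, had means of 256 and 674 TPM, a log2 ratio of 1.39 (1.19, 1.65 and 1.31 within sets). H2-D1 had 29.4 and 68.7 TPM (1.20). H2-K1 had 42.9 and 51.4 TPM (0.25), and its sign turned to -0.39 with means of log values, to -0.05 after centring on the all-gene median and to -0.18 without low-share cells, where B2m stood at 0.92 and H2-D1 at 0.79. H2-K1 was above 0 in 96 of 100 Ecad+ cells (90.1% to 98.9%) and 85 of 97 Ecad- cells (79.4% to 93.4%). Tapbpl stood at 0.70. Tapbp stood at 0.75 and at -0.0043 with means of log values. Class I genes are close paralogs, and kallisto can split reads among them, so values of single H2 genes are uncertain. H2-D1 lies on chromosome 17 at 35262730 to 35267499 and H2-K1 at 33996017 to 34000347.

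Proliferation genes were lower in Ecad- cells. All 40 G2/M genes lay below the all-gene median under the main setting, and 26 were lower in each library set. Their median was -1.39 at percentile 0, with -0.32, -2.13 and -1.88 within sets and -0.90 without set 2. Ube2c, a mitotic ubiquitin-conjugating enzyme, had 555 and 90.1 TPM (log2 ratio -2.61). Kif23 stood at -1.87, Cdk1 at -1.85 and Aurkb at -1.69. Mki67, the gene of the Ki-67 proliferation marker, was above 0 in 75 of 100 Ecad+ cells (65.3% to 83.1%) and 43 of 97 Ecad- cells, or 44.3% (34.2% to 54.8%). Its means were 9.88 and 3.62 TPM. The lower number of genes above 0 in Ecad- cells bears on such shares. Of 31 G1/S genes, 27 lay below the all-gene median. That list's median was -0.75 at percentile 0, with -0.42, -0.72 and -1.17 within sets. Rrm2 stood at -1.58 and Mcm5 at -1.02, whereas the DNA polymerase gene Pola1 stood at 1.14.

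Among 13 inhibitors of cyclin-dependent kinases and p53 targets, the median was -0.05 at percentile 44.5, 0.06 with the trimmed mean and 0.15 without low-share cells. Members differed widely. Gadd45a stood at 3.00, Trp53inp1 at 2.16, Gadd45b at 2.12 and Cdkn1a, which encodes p21, at 1.89 (34.3 and 130.2 TPM), or 0.69 without low-share cells. Genes driven by MAPK signalling were lower, with 12 of 14 below the all-gene median and a list median of -0.91 at percentile 0, or -0.53 at percentile 0.04 without low-share cells. Ereg and Ccnd1 stood at -1.41 and -1.40 and Phlda1 at -0.89, while Dusp4 stood at 2.19.

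**Figure D2:**
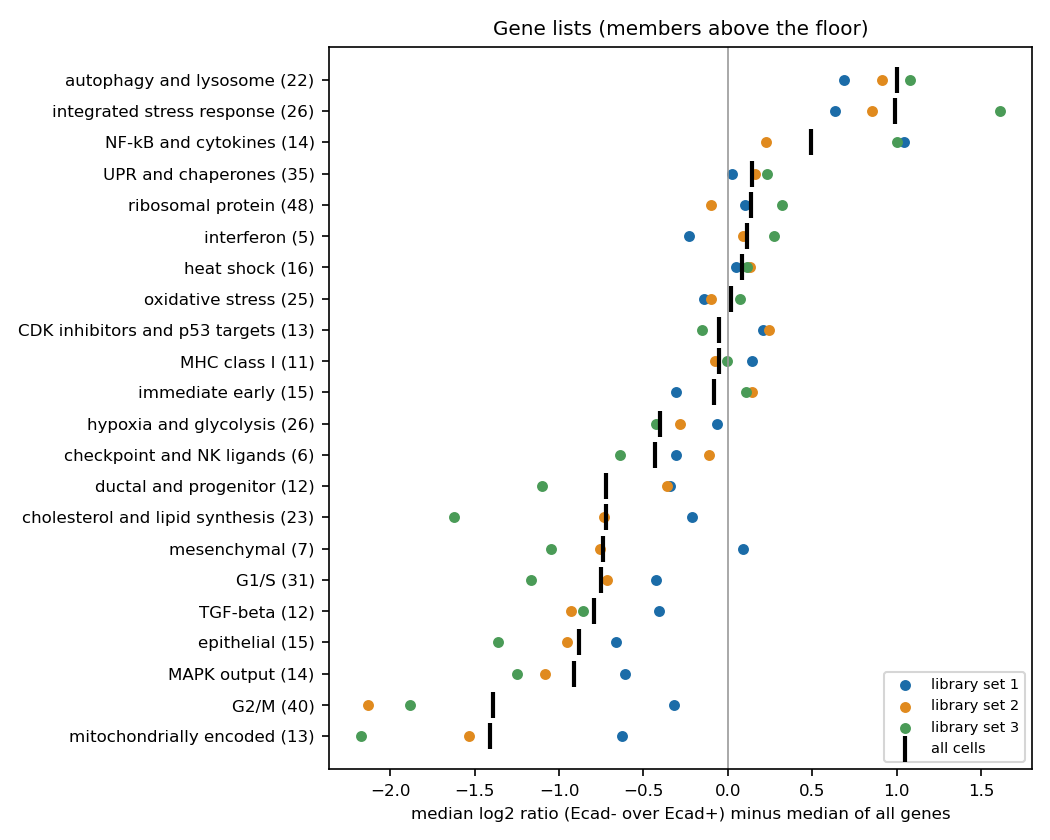
Median log2 ratio of gene lists with at least 5 members above the floor, without the marker lists of other cell types, minus the median of all genes, on the horizontal axis, with the number of members above the floor in brackets. Coloured points are the 3 library sets and black bars all cells. Autophagy and lysosome genes (1.00) and integrated stress response genes (0.99) lie farthest to the right of the lists drawn, and G2/M (-1.39) and mitochondrially encoded genes (-1.41) farthest to the left.

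All 13 mitochondrially encoded messenger RNAs were lower in Ecad- cells, each of them in each library set. The list median was -1.41 relative to all genes at percentile 0, with -0.63, -1.53 and -2.17 within sets. The median mitochondrial share of TPM was 30.0% in Ecad+ cells (quartiles 22.1% and 42.4%) and 8.78% in Ecad- cells (quartiles 0.144% and 26.2%). Within sets 1 to 3 it was 29.7%, 44.0% and 23.2% in Ecad+ cells and 21.2%, 12.6% and 0.194% in Ecad- cells. A share under 1% was seen in 1 of 100 Ecad+ cells and in 40 of 97 Ecad- cells, or 41.2% (exact 95% interval 31.3% to 51.7%). mt-Cytb stood at -1.45, mt-Co1 at -1.27, mt-Co3 at -1.22 and mt-Nd5 at -1.21. mt-Atp8 alone took a median of 23.8% of TPM in Ecad+ cells. Its annotated transcript is 204 nucleotides long, and its mean was 16.5 times that of mt-Atp6 in Ecad+ cells and 15.5 times in Ecad- cells. The TPM of so short a transcript depends on the length correction.

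**Figure D3:**
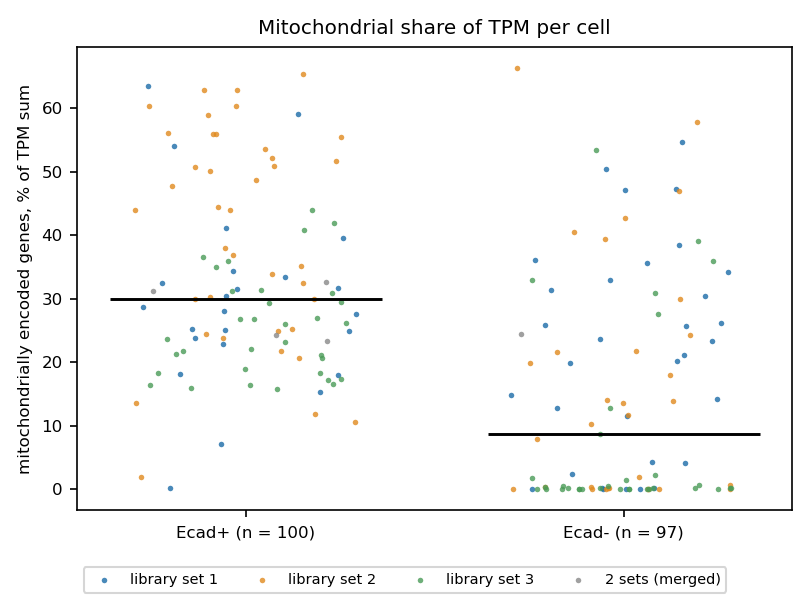
Share of each cell's TPM sum assigned to mitochondrially encoded genes, in percent, for 100 Ecad+ and 97 Ecad- cells coloured by library set. Black lines are the group medians of 30.0% and 8.78%, and 40 Ecad- cells lie under 1%.

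Cholesterol and lipid synthesis genes were lower, with all 23 members below the all-gene median under the main setting and a list median of -0.72 at percentile 0. The within-set medians were -0.21, -0.74 and -1.62, and the median was -0.38 without set 3 and -0.32 without low-share cells. Without these cells the within-set medians were -0.16, -0.28 and -1.38. Scd2 stood at -1.07, Nsdhl at -0.93, Srebf2 at -0.86 and Scd1 at -0.73. The TGF-beta list had a median of -0.80 at percentile 0.02, or -0.55 without low-share cells, with 9 of 12 members below the all-gene median. Id1 stood at -1.55, Id3 at -1.19 and Ctgf at -1.12, and Skil, a repressor of SMAD signalling, at 1.34. Ductal and progenitor genes had a median of -0.72 at percentile 0.1, with -0.34, -0.36 and -1.10 within sets, -0.42 without set 3 and -0.27 without low-share cells. Named members were Car2 at -1.22, Hnf4a at -1.05, Prom1 at -0.92 and Aldh1a3 at 0.99. Hypoxia and glycolysis genes had a median of -0.40 at percentile 0.26, with -0.07, -0.28 and -0.42 within sets. It was -0.11 at percentile 13.6 with means of log values, -0.23 without set 3, and -0.26 without low-share cells. Car9 stood at -1.78 and Pfkl at -0.93, but Ndrg1 at 2.14 and Vegfa at 1.28.

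The NF-kB and cytokine list had a median of 0.49 at percentile 99.4, with 11 of 14 members above the all-gene median. Within sets it was 1.04, 0.23 and 1.00, and it was 0.15 without set 1 and 1.04 without set 2. The placing depended on high values in few cells: with the trimmed mean the list median was 0.06 at percentile 66.2. Ccl20 was above 0 in 7 Ecad+ and 17 Ecad- cells, with a log2 ratio of 3.13. Cxcl16 stood at 1.73. Cxcl1 stood at 2.25 but was above 0 in 53 Ecad+ and 35 Ecad- cells, and at 0.085 with means of log values. Nfkbia stood at 1.47, and at -0.17 with means of log values. Of 29 interferon genes, 5 were above the floor, and their median was 0.11 at percentile 62.9, -0.17 with means of log values and 0.35 without low-share cells. Cxcl10 had means of 0.899 and 153 TPM from 7 Ecad+ and 13 Ecad- cells above 0. Its SD over Ecad- cells was 1369 TPM, and its log2 ratio of 6.34 was 2.46 with the trimmed mean and 0.60 with means of log values. Bst2 stood at -1.15, Irgm1 at -0.66 and Xaf1 at 0.88.

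Ligands of immune checkpoints and natural killer cell receptors had a median of -0.43 at percentile 6.31 over 6 members, and -0.11 without low-share cells. H2-T24 stood at 1.53 and Pvr at 1.47. Lgals9 stood at -1.21 (205 and 88.1 TPM). Cd47 stood at -0.25, and at 0.01 without library set 3. Immediate early genes had a median of -0.08 at percentile 31.8, with 7 members above and 8 below the all-gene median, 0.09 without set 1, and -0.27 without low-share cells. Fos stood at -1.71, Maff at 1.67, Btg1 at 1.64 and Klf6 at 1.17. Heat shock genes had a median of 0.08 at percentile 66.0, -0.02 with the trimmed mean and -0.04 without low-share cells. Hspa1a stood at 3.55 but at -0.29 in set 1, at 0.19 with the trimmed mean and at -0.14 without low-share cells, Hsp90aa1 at 0.88, Dnajb4 at 1.13, and Hspa1b at 2.85, or -0.28 with means of log values and 0.15 without low-share cells. Oxidative stress genes had a median of 0.02 at percentile 53.7, -0.07 with the trimmed mean and 0.17 without low-share cells. Hmox1 stood at 2.03 and Mt2 at 1.59, while the glutathione transferase genes Gsta4 and Gsta1 stood at -1.95 and -1.66. Gsta1 was higher in set 2, at 0.52. Ribosomal protein genes had a median of 0.13 at percentile 89.1, with -0.10 in set 2. It was 0.0043 without set 3, 0.23 without set 2 and 0.034 without the 10% of cells with the fewest genes. Rps27 stood at 1.11, Rpl26 at 0.80, and Rps14 and Rpl34 at 0.79.

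Ranked by their smallest ratio over the 3 library sets, the 10 genes higher in Ecad- cells were Ddit3, Hist1h4h, Lrrc41, Crebrf, Hexa, Fnip1, Ppp1r15a, Mfsd1, Mospd1 and Ifrd1. Hist1h4h stood at 3.89, Lrrc41 at 3.21, Fnip1 at 3.13, Ifrd1 at 2.87, Mospd1 at 2.86 and Mfsd1, a lysosomal membrane protein gene, at 2.80. Without low-share cells these 6 genes stood at 2.36, 1.60, 1.65, 2.22, 1.66 and 1.55 in the same order. Hist1h4h was above 0 in 38 Ecad+ and 41 Ecad- cells, and histone genes have near-identical copies. The 10 lower genes were Ctse, Cldn7, S100a14, Msln, Paqr5, Rgl1, Efemp1, Rfc5, Krt20 and Tm4sf20. Ctse, an aspartic protease gene, had 107 and 18.2 TPM (log2 ratio -2.48). Paqr5 stood at -2.10, S100a14 at -2.03, and Msln, which encodes mesothelin, at -1.94. Efemp1 stood at -1.94, Krt20 at -1.80, Rfc5 at -1.70, Tm4sf20 at -1.56 and Rgl1 at -1.52.

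Markers of other cell types were mostly low in both groups. Of 19 immune markers, 14 had means under 1 TPM in both groups. The 2 above the floor were higher in Ecad- cells, Cd68 at 2.08 (6.35 and 30.0 TPM) and S100a8 at 1.99 (2.19 and 11.7 TPM). Their median was 1.73 relative to all genes at percentile 99.7, and 1.34 without low-share cells, with -0.15 in set 3. S100a8 was above 0 in just 13 Ecad+ and 17 Ecad- cells. Cd74, below the floor, had means of 0.012 and 4.46 TPM. Cd68 encodes a lysosomal membrane protein and so also bears on the lysosome genes. All 13 fibroblast markers and all 12 acinar and endocrine markers had means under 1 TPM in both groups. Of 10 endothelial markers Egfl7 was above the floor, at -0.80 and percentile 4.85, but at 0.10 in set 1. Relative to all genes it stood at -1.11, at -0.63 without set 3, at -1.73 without set 1 and at -0.62 without low-share cells. Of 11 hepatocyte markers found, Apob stood at -1.08, Cyp2e1 at 0.98, and Ttr at 0.40 or -0.57 with the trimmed mean. Their median was 0.10 at percentile 62.5, with -0.96 in set 1 and 0.90 without low-share cells. It turned to -0.78 with the trimmed mean, -0.49 without set 3 and -0.17 with means of log values, so it has no stable sign.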

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

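No paired analysis was possible because the numbers in the sample titles only count cells, so no replicate block can be fitted. Ratios within each library set, which holds both groups, stand in its place. They remove an effect of the suffix only, since the groups share no library number. Results were compared by whether they moved by more than 1 SD of the values in the 3 library sets. Of 172 alternative values for the main results, 149 stayed within that spread and 23 moved beyond it. The main results here include the autophagy and mitochondrial lists, which were classed as other lists and not as main ones. The more the sets disagree, the wider that spread, so the count alone is no measure of stability. The SD was 0.86 for G2/M and 0.72 for mitochondrial genes, but 0.055 for class I genes. The list medians below are not centred unless said. Means of log values gave -2.07 for Cdh1 and -1.17 for epithelial, -0.39 for class I, -0.024 for unfolded protein response, -1.14 for G1/S, -1.98 for G2/M, 0.83 for autophagy and -4.05 for mitochondrial genes. This measure weighs cells at 0 more, and Ecad- cells had fewer genes above 0. Centring gave -0.053 for class I, 0.14 for unfolded protein response and 1.00 for autophagy genes, by construction 0.31 lower. Rescaling without mitochondrial and ribosomal protein genes gave -0.093, 0.15 and 0.91 for the same lists, and rescaling without mt-Atp8, chosen after seeing the data, gave -0.0015, 0.22 and 1.02. For class I genes the trimmed mean gave 0.37, no floor 0.048, and leaving out the 10% of cells with the fewest genes, also chosen afterwards, 0.46. Leaving out cells with a mitochondrial share under 1%, chosen afterwards too and not applied to mitochondrial genes, gave 0.59 for autophagy genes. A floor of 50 TPM gave -1.35 for epithelial genes, which leaves fewer members. The gap in genes per cell was -175.5 at 10 TPM. Where no construction is named, the cause was not tested.

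The stress response list median ranged from 0.87 to 1.54 over its alternatives, and Cdh1 from -2.07 to -0.88. Means of log values turned the sign of 3 named genes with 1 sign in all library sets, Tapbp (-0.0043), Hspa1b (-0.28) and Nfkbia (-0.17), and of the NF-kB list (-0.15). They also made 6 further lists negative that were positive in each set but lay within the central 95% of random lists: class I and unfolded protein response (above), cell cycle inhibitors (-0.39), heat shock (-0.27), oxidative stress (-0.24) and mitochondrial expression (-0.20). The all-gene median moved to -0.28 under this measure. The cause was not tested. Among other results, 238 values moved and 1865 did not. Leaving out cells with fewer than 2000 genes removed none, since the lowest cell had 4168, so that filter says nothing about stability. Thinning was not run, since it needs counts. Read depth is unknown, which leaves open how far genes at 0 reflect depth.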

Other observations

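The tests with mt-Atp8 left out, within library sets, with the TPM scale reset and with immediate early genes were chosen after the results were seen, as were the 4 further gene lists here. One of them was assembled once lysosomal genes had been seen to be high, so it describes those genes and is no independent evidence. Its 27 genes come from the vacuolar proton pump, lysosomal enzymes and lysosomal nutrient sensing. Of these, 26 lay above the all-gene median and 24 were, not centred, higher in Ecad- cells in each library set. Their median was 0.87 relative to all genes, with 0.90, 0.99 and 1.30 within sets, and 0.49 without cells of a mitochondrial share under 1%. Pump subunits included Atp6v1d (56.0 TPM in Ecad+ and 334 in Ecad-, log2 ratio 2.56) and Atp6v0b (226 and 1248 TPM, 2.46). Flcn, Fnip1 and Rragc, which act in nutrient sensing at the lysosome, stood at 2.18, 3.13 and 2.59.

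Nuclear genes of mitochondrial function did not share the direction of the mitochondrial genome. The median of 40 nuclear genes of the respiratory chain was 0.13 relative to all genes at percentile 81.4, with 0.17, 0.23 and 0.12 within sets, and 0.04 without cells of a mitochondrial share under 1%. It was 0.21 without set 3 and 0.50 at percentile 94.5 with means of log values. For 17 genes of mitochondrial transcription, translation and DNA maintenance the median was 0.07 at percentile 63.0, with -0.07 in set 1. It was 0.10 without cells of a share under 1%, 0.15 without set 2 and 0.18 without set 3.

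The first pattern is the lower mitochondrially encoded RNA in Ecad- cells. Inflated TPM of the short mt-Atp8 transcript would move all other genes of a cell alike. The other 12 mitochondrial genes had a median of -1.21 relative to all genes after rescaling without mt-Atp8. A shift common to all genes largely cancels in that difference, and the whole list already stood at -1.41. The value could thus hardly have come out otherwise and is weak evidence. Such inflation, which was not itself shown, would enlarge the mitochondrial share. Library set alone does not account for the lower level, since the highest within-set median was -0.47, although sets differ in size of effect. This covers the suffix only. A batch that follows the library number cannot be told apart from the sorted group. Loss of cytoplasm from Ecad- cells stays open. Nuclear-retained long RNAs minus ribosomal protein genes came to 0.78, between the values set for and against it, over just 4 long RNAs. Within sets 1 to 3 the long RNAs stood at 0.88, 1.53 and 0.96, and the ribosomal protein genes at 0.26, 0.34 and 0.58. Without low-share cells and relative to all genes they stood at 0.46 and 0.15, a smaller gap. The outcome of this comparison therefore depended on the set and on the low-share cells. A difference tied to the E-cadherin state stays open, as untested.

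The second pattern is the higher integrated stress response in Ecad- cells. A shift of the TPM scale by mitochondrial RNA would leave the list near 0 once mitochondrial and ribosomal protein genes were left out of each cell's total. Its median, not centred, was then 1.08, while that of all genes went from 0.31 to 0.0064. The list already stood at 0.99 relative to all genes, so this outcome was largely known beforehand. A few extreme cells were argued against by the trimmed mean, at 1.14 above all genes. Stress of dissociation and sorting could raise both immediate early and stress genes; the immediate early median was -0.081 relative to all genes, but its members went both ways, so this stays open. Stress in culture before the sort is a further hypothesis that these data cannot separate from it.

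The third pattern is across cells, which are not independent samples, so no p-value is given. In Ecad- cells the mean log2 level of the stress response genes, rescaled without mitochondrial and ribosomal protein genes, was lower where the mitochondrial share was higher: Spearman's rho was -0.22, -0.46 and -0.54 and Pearson's r -0.33, -0.49 and -0.60 in sets 1 to 3. Without the 2 cells farthest from the median share, r was -0.21, -0.45 and -0.57. The highest rho, -0.22, misses the bound of -0.3 set for each set. Given the number of genes above 0, the partial rank correlation was -0.41 over all Ecad- cells with -0.06, -0.45 and -0.53 in sets 1 to 3. In sets 2 and 3 this number thus did not carry the whole relation. Read depth is unknown, so detection as a cause stays open. In set 1 the relation cannot be told apart from the number of genes above 0. In Ecad+ cells rho was -0.61, -0.44 and -0.21, r was -0.66, -0.45 and -0.099, and r without the 2 farthest cells was -0.67, -0.26 and -0.0056. The partial rank correlation was -0.39 over all Ecad+ cells, with -0.64, -0.49 and -0.26 in sets 1 to 3. The relation was thus seen in Ecad+ cells too, most in sets 1 and 2. In set 3 of Ecad+ cells rho was about that of set 1 in Ecad- cells, though r was weaker.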
